A study of Homo sapiens with 6 samples.

How the data were processed

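The study measured total RNA of cultured human T lymphocytes from 3 donors on Affymetrix HG-U133 arrays of type A, with 1 array per culture and 6 arrays in all. Per the labels' source descriptions, the cells had been activated through CD3 together with interleukin 2. Per the titles, 3 arrays came from static cultures and 3 from cultures in modeled microgravity (MMG). The deposited values were RMA expression values on the log2 scale, per the submitters' processing notes, which name RMA without a version. RMA corrects background on each array, normalizes the arrays to one another by quantiles and summarizes the probes of each probe set. The log2 scale was read from the range of the deposited values. The scanner files were not used here, so the background correction and the summary of probes were not redone, and no detection call was used. The number of arrays sets the precision of every value.

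The table held 22283 probe sets, of which 68 were control probe sets. A platform annotation gave exactly 1 gene symbol to 19065 of the others, several symbols to 1043 and listed none for 2107. By gene ID, 19053 of the probe sets with 1 gene were found in a RefSeq gene table of the GRCh38.p14 assembly, which was used for names only, and 0 symbols needed an update. Each gene was represented by the probe set with the highest mean over the 6 arrays among those with exactly 1 symbol, which left 11939 genes. XIST, TSIX and Y-linked genes were left out because the donors are people. There was no filter on dim probe sets.

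The series design states that each donor gave 1 static and 1 MMG culture, so donor was a block in the model. Numbers in the titles gave the pairs of donors 2 and 3. The titles of 1 static and 1 MMG array carry no number, and these were taken as the pair of donor 1, the donor left in the series design. As a check, the deviations of the same donor's 2 arrays from their group means correlated across genes at 0.544, 0.458 and 0.298 for donors 1, 2 and 3. Between a static and an MMG array of different donors these correlations lay between -0.435 and 0.089. By the plain correlation of values, though, the static array of donor 3 was closer to the MMG array of donor 1 (0.9875) than to its own (0.9851). Genes are not independent replicates, so these values describe the arrays only. The difference MMG minus static was fitted with lmFit and moderated with eBayes in limma 3.58.1 (R 4.3.3), with 2 residual and 5.27 prior degrees of freedom. Adjusted p-values are from this limma model with the Benjamini-Hochberg adjustment over 11939 genes, and all tests were two-sided. A change was called at an adjusted p under 0.05. The error beside a change is the SD of the 3 donor differences.

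Besides the test, genes were counted whose difference was at least 1.5-fold with the same sign in each of the 3 donors. As a level without a shared direction, the same count was made with the differences of 1 donor turned round. A total of 33 gene lists, fixed before the data were examined together with the tests and the naming rule, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With the correlation estimated, camera takes its p from the 2 residual degrees of freedom, so that few lists could pass whatever their correlation. For each list, members past the threshold were counted over all genes and adjusted over the list alone.

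The text names the 12 higher and the 12 lower genes with the smallest moderated p among those past the threshold, with the same sign in all 3 donors and a mean in the higher group at or above the 40th percentile of all genes (a log2 value of 6.77). Where fewer than 12 passed, the places were filled with genes that met the other conditions without passing, and the text says so. In addition up to 4 members of each list were named, those with the smallest moderated p. Genes outside this rule are marked as chosen after their values were seen.

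The model and the list test were tested on simulated data made from the spread of these arrays, for the comparison of MMG with static cultures over 11939 genes. Of genes changed by 0.5 on the log2 scale 21.4% (12 of 56) were called, of those changed by 1 95.4% (62 of 65), and of those changed by 2 100% (79 of 79). Of 11700 unchanged genes 9 were called. The simulation held 200 changed genes besides the shifted list, so its adjustment allowed a looser p than in the real arrays, where 17 genes passed. Nor did it hold a dependence on brightness. These shares may thus be too high for the real arrays, where HMOX1 at 1.20 passed but GZMB at -1.56 and NQO1 at 1.03 did not. A list shifted by -0.5 was called, and 0 of 32 other lists were. The simulated genes varied independently of one another, so this could not test false list calls that come from correlation between members.

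Alternatives recomputed the gene counts, the list tests and the changes of named genes without the donor block, without each donor, after quantile normalization or median centring of the deposited values, with a filter on dim probe sets, with the mean of a gene's probe sets, without probe sets of the x_at type, with a trend of the prior variance on expression, and at other thresholds. An offset of 16 on the linear scale was tried for the gene counts, and single probe sets were also tested on their own. The count of 1.5-fold genes has no alternative for the block or the trend, which it does not use, and the monocyte list was not tested with the filter on dim probe sets. Cyclic loess between arrays was added after seeing that the change depended on a gene's brightness. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.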

Results

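Gene expression was compared between activated human T cells kept in modeled microgravity (MMG), a culture condition meant to imitate weightlessness, and cells of the same donors in static culture at normal gravity. Per its title, the study asked how this condition changes genes of apoptosis, or programmed cell death. Each of 3 donors gave 1 static and 1 MMG culture, and each culture was measured on 1 array, so that there were 3 arrays per group. The culture device and the time in culture are not given in the sources used here. Median log2 values of the arrays lay between 6.79 and 6.90. All changes below are MMG minus static on the log2 scale, as mean ± SD over the 3 donor differences.

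In MMG the mRNA of RBM3, an RNA-binding protein that is induced by mild cold, fell 4.43-fold (-2.15 ± 0.34, n = 3 donors, adjusted p = 0.00750). A second RBM3 probe set gave -0.38, and the mean of both gave -1.26 (adjusted p = 0.0400). HMOX1, which encodes the heme-degrading stress enzyme heme oxygenase 1, rose 2.30-fold (1.20 ± 0.25, n = 3 donors, adjusted p = 0.0430), and the histone gene H2AC6 rose 2.73-fold (1.45 ± 0.42, n = 3 donors, adjusted p = 0.0430). Both chains of the interleukin 18 receptor fell, IL18R1 by 0.86 ± 0.05 and IL18RAP by 0.84 ± 0.16. The cytotoxic granule genes GNLY (granulysin) and GZMA (granzyme A) fell by 0.90 ± 0.08 and by 0.76 ± 0.08.

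In all, 17 of 11939 genes passed an adjusted p under 0.05 in the limma model with donor as a block, 2 higher and 15 lower, each with the same sign in all 3 donors. Besides those above, the lower genes named by rule were SMYD3, a lysine methyltransferase (-1.19 ± 0.34), KYAT3, a kynurenine aminotransferase (-1.03 ± 0.21), and VRK1, a nuclear kinase (-0.84 ± 0.14). They also included the chemokine gene CCL22 (-0.73 ± 0.04) and RRP15, a factor of ribosome assembly (-0.84 ± 0.11), of which another probe set gave -0.34. The zinc transporter gene SLC39A8 (-0.88 ± 0.18) and the polyadenylation factor gene CPSF6 (-0.95 ± 0.21) were lower as well, but another probe set of each gave 0.06 and 0.17. With the mean of a gene's probe sets RRP15 (-0.59, adjusted p = 0.0727), SLC39A8 (-0.33, adjusted p = 0.149) and CPSF6 (-0.39, adjusted p = 0.108) did not pass. The 3 genes outside the naming rule, chosen after their values were seen, were CD2AP (-0.83 ± 0.17), MRTFB (-0.76 ± 0.11) and COQ2 (-0.71 ± 0.05). Except for RBM3, the adjusted p of these genes lay between 0.0430 and 0.0478, close to the threshold. Without the donor block 0 genes passed (smallest adjusted p 0.117, with 1657 genes at an unadjusted p under 0.05), whereas with it 2592 genes had an unadjusted p under 0.05. Without donor 1, 2 or 3 the number was 41, 952 or 3, and the 3 genes that passed without donor 3 were RBM3, HMOX1 and H2AC6. The quantile-normalized values gave 7 genes, 2 higher and 5 lower, and cyclic loess, added after seeing the data, gave 18, 4 higher and 14 lower.

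**Figure D1:**
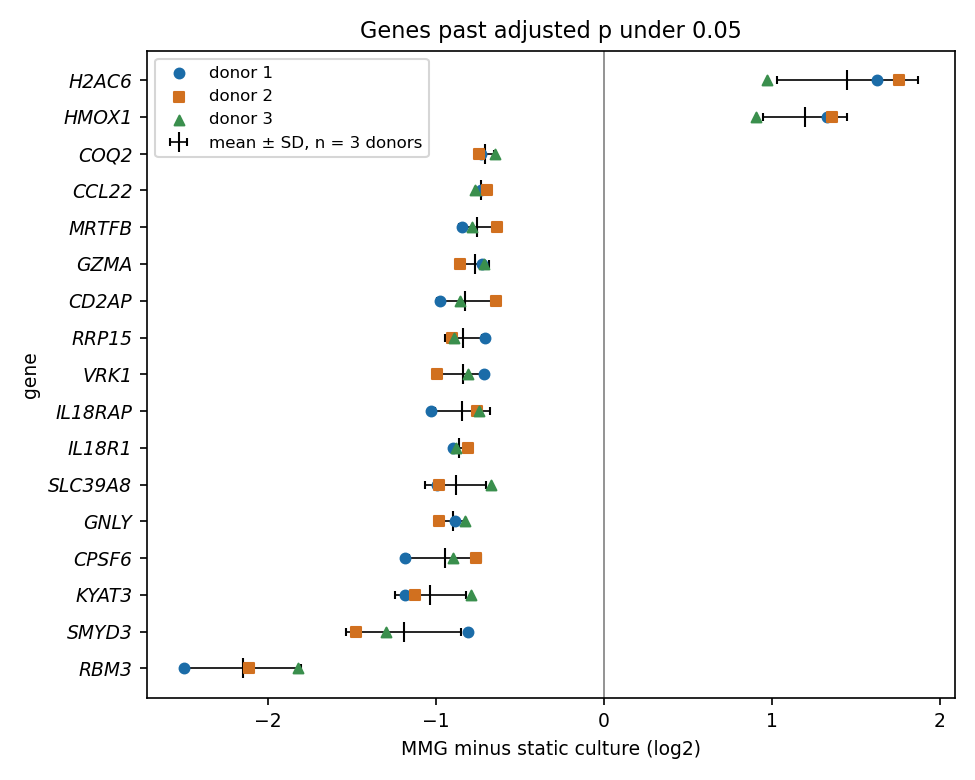
MMG minus static difference on the log2 scale (horizontal axis) of the 17 genes past an adjusted p under 0.05 (vertical axis), with 1 symbol per donor and the mean ± SD of the 3 donors as a bar. All 3 donors lie on the same side of 0 for each gene, and RBM3 has the largest difference, a mean of -2.15.

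A further 10 places of the naming rule among higher genes were filled by genes that did not pass, at adjusted p between 0.0511 and 0.0651. FTL, the light chain of the iron store ferritin, had a difference of 0.79 ± 0.19, and NQO1, a quinone reductase, one of 1.03 ± 0.54. SLC48A1 and ABCB6, which encode a heme and a porphyrin transporter, differed by 0.54 ± 0.15 and 0.71 ± 0.16. Another probe set of SLC48A1 gave -0.06, and another of ABCB6 gave 0.12. The others were the histone gene H2BC5 (0.97 ± 0.38), the interleukin 7 receptor gene IL7R (0.74 ± 0.28), LY9 (0.80 ± 0.33), PFN2 (0.56 ± 0.04), PEX6 (0.62 ± 0.22) and the chaperone gene HSPH1 (0.57 ± 0.17). Another probe set of H2BC5 gave 0.44, and another of PEX6 gave 0.35.

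By the median of the genes' mean changes, the S phase and the G2 and mitosis lists shifted most among the 33 fixed gene lists. In donor 2, though, the NF-kB list (-0.292) and activation markers (-0.287) had lower medians than the S phase list (-0.268). In the S phase list, 38 of 39 measured genes had a lower mean in MMG, with a median change of -0.47. None passed over all genes tested, but 33 were lower when adjusted over the list alone, among them POLE2 (-0.76), RFC5 (-0.63), RFC3 (-0.67) and GINS2 (-0.86), which encode parts of the DNA replication machinery. The list was lower than other genes in camera with a preset correlation (adjusted p = 9.64e-20), but not when the correlation was estimated (adjusted p = 0.384 with an estimated correlation). In the G2 and mitosis list 42 of 47 genes had a lower mean, with a median of -0.36, and 13 were lower adjusted over the list alone, 0 over all genes. The spindle and chromosome genes MAD2L1 (-0.84), KIF11 (-0.88), SMC2 (-0.60) and DLGAP5 (-0.87) had the smallest p. This list's adjusted p was 5.19e-10, and its adjusted p = 0.431 with an estimated correlation. Its median differed between donors, at -0.72, -0.01 and -0.36 for donors 1, 2 and 3, and was -0.18 without donor 1 and -0.58 without donor 2. B-cell markers had medians of -0.47, -0.02 and -0.23 in the same donors. Of 22 cyclins D and cell cycle inhibitors, 3 were lower and 1 was higher adjusted over the list alone, with RB1 at -0.70, CCND2 at -0.35, CDK2 at -0.42 and KLF2, a quiescence factor, at 0.49. This list was lower at adjusted p = 0.00401 (median -0.21, and adjusted p = 0.384 with an estimated correlation), but not with the mean of a gene's probe sets (median -0.06, adjusted p = 0.0863).

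**Figure D2:**
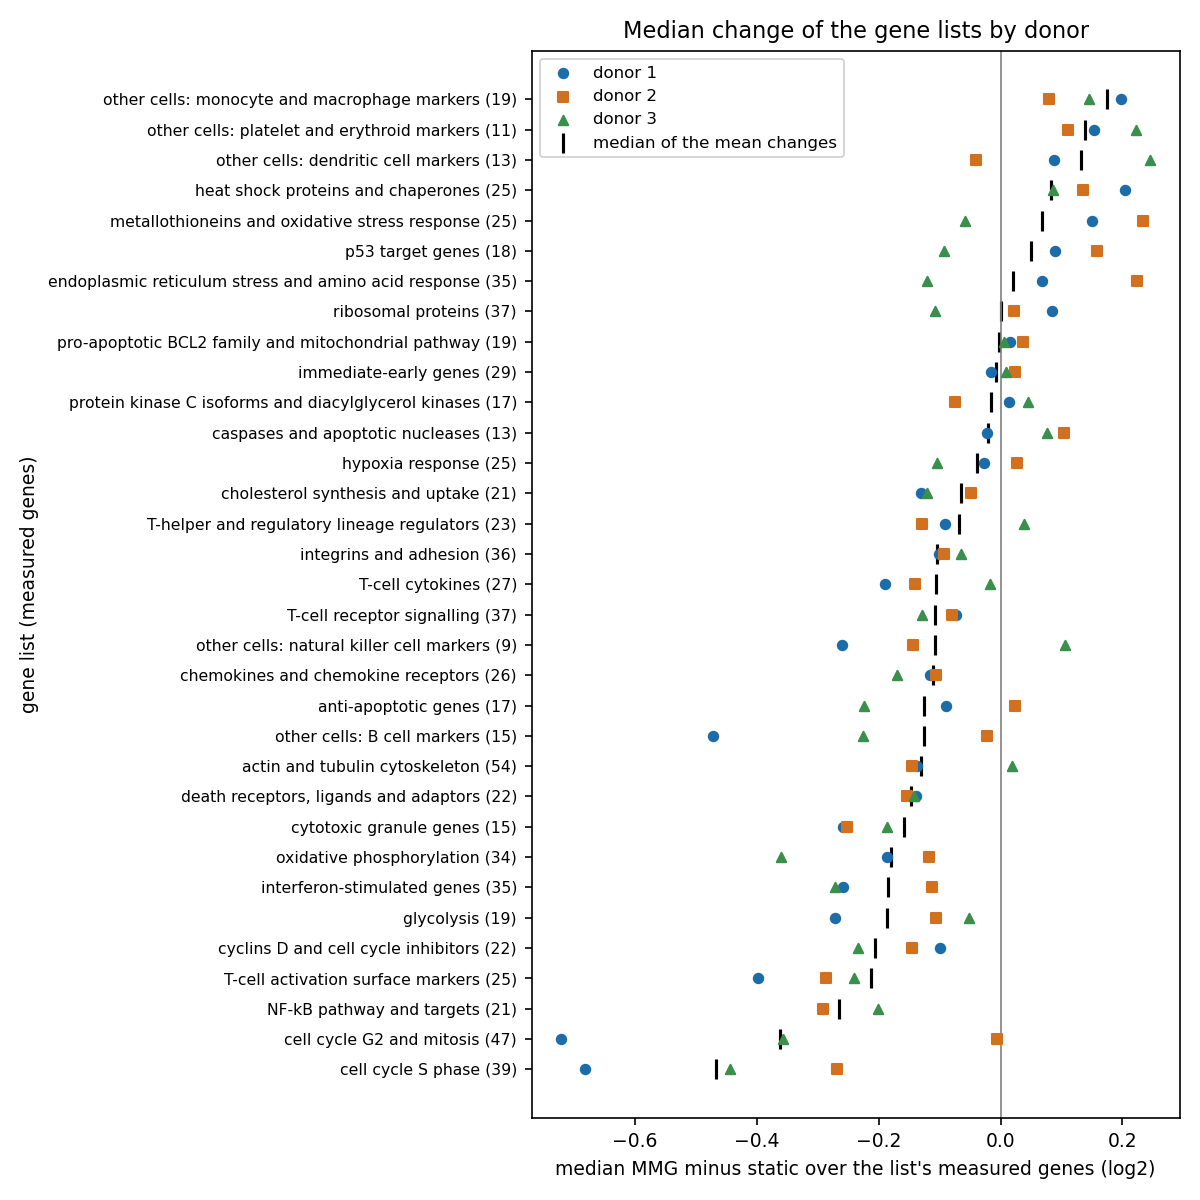
Median MMG minus static change on the log2 scale (horizontal axis) over the measured genes of each of the 33 gene lists (vertical axis, number of measured genes in brackets), with 1 symbol per donor and a black mark for the median of the genes' mean changes. The S phase list is lowest in the black marks (-0.47) and lies below 0 in each donor, whereas the G2 and mitosis list is near 0 in donor 2.

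Most markers of T-cell activation had a lower mean in MMG. Of 25 measured surface markers 24 had a lower mean (median -0.21), and 9 were lower adjusted over the list alone, 0 over all genes. The costimulatory receptor gene TNFRSF4 (OX40) was at -0.59, but a probe set that is not of the x_at type gave 0.10. The transferrin receptor gene TFRC was at -0.92 ± 0.36, the early activation marker CD69 at -0.74 and the MHC class II gene HLA-DRA at -0.71. HLA-DRA is also high in B cells, and its changes of -1.04, -0.25 and -0.85 in donors 1, 2 and 3 stood beside -0.65, -0.15 and -0.32 for the B-cell marker MS4A1. Camera gave an adjusted p of 2.33e-07, and adjusted p = 0.384 with an estimated correlation. The median was -0.35 without donor 2, -0.14 after quantile normalization and -0.13 with cyclic loess. In the list of the NF-kB pathway and its targets, 20 of 21 genes had a lower mean (median -0.26) and 7 were lower adjusted over the list alone, with IRF1 at -0.52, the inhibitor gene NFKBIA at -0.41 and the target genes BCL2A1 at -0.65 and CD83 at -0.41. The call (adjusted p = 3.02e-07) did not hold when the correlation was estimated (adjusted p = 0.384 with an estimated correlation). Of 35 interferon-stimulated genes 29 had a lower mean (median -0.19), and adjusted over the list alone 12 were lower and 1 higher. The guanylate-binding protein gene GBP1 was at -0.99, the antigen processing genes TAP1 and PSMB9 at -0.91 and -0.72, and the antiviral gene MX1 at -0.57 (list adjusted p = 2.33e-07, and adjusted p = 0.431 with an estimated correlation).

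Among T-cell cytokines 8 of 27 genes were lower adjusted over the list alone, 0 over all genes, including CSF1 (-0.82), LTA (-0.82), TNFSF10 (-0.54) and OSM (-0.50). The list had a median of -0.11 and an adjusted p of 0.0110, with adjusted p = 0.431 with an estimated correlation. Its adjusted p was 0.118 without the donor block, and without donor 2 its median was -0.0042 (adjusted p = 0.0557). The median was -0.05 without donor 1, -0.16 without donor 3, -0.16 with median centring and -0.38 with the filter on dim probe sets. Among chemokines and their receptors 7 of 26 were lower and 1 was higher adjusted over the list alone, and CCL22 passed over all genes. CXCR3, the receptor of interferon-induced chemokines, was at -0.71, XCL1 at -0.63 and CCL20 at -0.62. The list's median was -0.11 (adjusted p = 0.00195, and adjusted p = 0.384 with an estimated correlation), and it was -0.17 with median centring and -0.26 with the filter on dim probe sets.

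The cytotoxic granule genes moved unequally. Of 15 genes 7 were lower and 1 was higher adjusted over the list alone, and GNLY and GZMA passed over all genes. Granzyme B (GZMB) differed by -1.56 ± 0.88 and granzyme M (GZMM) by -0.54, whereas the perforin gene PRF1 differed by 0.03 ± 0.09 (adjusted p = 0.839). PRF1 was chosen after its value was seen, and its sign turned with median centring (-0.02) and without donor 3 (-0.02). The list's median was -0.16 (adjusted p = 0.000900, and adjusted p = 0.384 with an estimated correlation). Its call ended without the donor block (adjusted p = 0.0566) and with cyclic loess (adjusted p = 0.0548), and its median was -0.24 without donor 1, -0.06 after quantile normalization and -0.09 with cyclic loess. In the list of natural killer cell markers 2 of 9 genes were lower adjusted over the list alone, GNLY and XCL1, which activated T cells also express. That list was not called (median -0.11, adjusted p = 0.0563), but it was without donor 3 (adjusted p = 0.00567), without x_at probe sets (median -0.26, adjusted p = 0.0269), after quantile normalization (adjusted p = 0.0314), with the trend of the prior variance (adjusted p = 0.0410) and with cyclic loess (adjusted p = 0.0439).

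For the genes of apoptosis that the study's title names, no member of the 5 lists passed over all genes. Death receptors, their ligands and adaptors were lower as a list (median -0.15, adjusted p = 0.00195), but not with the other correlation (adjusted p = 0.384 with an estimated correlation). The median was -0.25 with the filter on dim probe sets. Adjusted over that list alone, 7 of 22 genes were lower and 1 was higher. The ligand genes TNFSF10 (TRAIL) and LTA were at -0.54 and -0.82, the TNF receptor gene TNFRSF1B at -0.73 and the adaptor gene TRAF3 at -0.29. The receptor gene FAS, chosen after its value was seen, was at -0.30 ± 0.09, lower in all 3 donors (adjusted p = 0.148 over all genes). Anti-apoptotic genes had a median of -0.13 over 17 genes and 0 past the threshold adjusted over the list alone, with BCL2A1 at -0.65, BCL2L2 at 0.27, PEA15 at -0.24 and BAG4 at -0.26. This list was just past the threshold (adjusted p = 0.0484, and adjusted p = 0.692 with an estimated correlation). Its call ended in 8 other alternatives, among them without the donor block (adjusted p = 0.0606), without donor 1 (adjusted p = 0.138) and without donor 3 (median -0.02, adjusted p = 0.491). Without donor 2 its median was -0.21. Pro-apoptotic BCL2 family genes as a list showed no shift in 1 direction (19 genes, median -0.0024, adjusted p = 0.818), with BCL2L13 at -0.38, BID at -0.40, APAF1 at 0.28 and BAX at 0.37. Caspases and apoptotic nucleases showed none either (13 genes, median -0.02, adjusted p = 0.970), with CASP10 at 0.23, CASP4 at -0.48 and CASP2 at 0.29. Of 18 p53 target genes, DDB2 (-0.65) was lower and SESN1 (0.46) higher adjusted over the list alone, PHLDA3 and TP53I3 were each at 0.28, and the list was not called (median 0.05, adjusted p = 0.627). In fry's test of change in either direction, pro-apoptotic genes (adjusted p = 0.0403), p53 targets (0.0307) and death receptors (0.0192) passed. Anti-apoptotic genes (0.106) and caspases (0.578) did not pass it.

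Genes of T-cell receptor signalling had a median of -0.11, and 30 of 37 had a lower mean. None passed adjusted over the list alone, with the RAS activator gene SOS1 at -0.41, NFATC3 at -0.42, NFATC1 at -0.34 and the adaptor gene LAT at -0.37. The list was lower at adjusted p = 0.00199 (adjusted p = 0.431 with an estimated correlation), but not after quantile normalization (adjusted p = 0.319), with a filter on dim probe sets (adjusted p = 0.0967) or with cyclic loess (adjusted p = 0.379). Its median was -0.0081 after quantile normalization, -0.013 with cyclic loess and -0.16 with median centring. In the list of protein kinase C isoforms and diacylglycerol kinases PRKCA was at -0.76, the only 1 of 17 past the threshold adjusted over the list alone, and the list was not called (median -0.02, adjusted p = 0.583). Immediate-early genes went both ways (median -0.01, 29 genes, adjusted p = 0.165). Adjusted over the list alone 4 were lower and 2 higher, with RGS1 at -0.82, KLF10 at -0.76, DUSP2 at -0.55 and MYC at 0.50. Regulators of T-helper and regulatory lineages were not called (23 genes, median -0.07, adjusted p = 0.126), with SOCS1 at -0.59 lower adjusted over the list alone and RORA at -0.29. Without donor 3 that list was called (adjusted p = 0.00567).

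Among the stress response lists, only that of heat shock proteins and chaperones was called with the preset correlation, as higher. Of 25 heat shock proteins and chaperones 9 were higher and 0 lower adjusted over the list alone, 0 over all genes, with HSPH1 at 0.57, HSPB1 at 0.77, DNAJB1 at 0.55 and DNAJB4 at 0.63. The list's median was 0.08 and its mean 0.19 (adjusted p = 0.00881, and adjusted p = 0.431 with an estimated correlation). Its call ended without the donor block (adjusted p = 0.108) and without donor 2 (median 0.16, adjusted p = 0.0557), and its median was 0.15 without donor 3, 0.14 after quantile normalization, 0.13 with cyclic loess and 0.03 with median centring. Of 25 metallothioneins and oxidative stress genes 5 were higher and 0 lower adjusted over the list alone, among them HMOX1, FTL, NQO1 and GCLC (0.37), the catalytic subunit of glutathione synthesis. The list as a whole was not called (median 0.07, adjusted p = 0.0711), but it was in 7 alternatives, with adjusted p = 0.0109 without donor 1, 0.000361 without donor 3 and 0.000109 with cyclic loess. Endoplasmic reticulum stress and amino acid response genes were not called (35 genes, median 0.02, adjusted p = 0.508), with DDIT4 at -0.50, ATF5 at -0.48, ERN1 at 0.49 and PSAT1 at 0.61. This list was higher without donor 3 (adjusted p = 0.00352), after quantile normalization (adjusted p = 0.0180) and with cyclic loess (adjusted p = 0.0103). Hypoxia response genes were not called (25 genes, median -0.04, adjusted p = 0.126), with 4 lower and 1 higher adjusted over the list alone, such as AK4 at -0.41 and MXI1 at 0.49.

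Most genes of the oxidative phosphorylation and glycolysis lists had a lower mean in MMG, by small amounts. Of 34 oxidative phosphorylation genes 33 had a lower mean (median -0.18), with NDUFS1 at -0.54, NDUFA9 at -0.37 and CYC1 at -0.35, and 0 passed adjusted over the list alone. Camera gave an adjusted p of 2.33e-07, and adjusted p = 0.431 with an estimated correlation. The list is bright, and its median was -0.10 with cyclic loess and -0.09 after quantile normalization. Of 19 glycolysis genes 3 were lower adjusted over the list alone, HK2 (-0.42), LDHA (-0.40) and PGAM1 (-0.38). The list had a median of -0.19 (adjusted p = 0.000843, and adjusted p = 0.431 with an estimated correlation) and lost its call without donor 1 (median -0.10, adjusted p = 0.0554) and with cyclic loess (median -0.11, adjusted p = 0.0738). Cholesterol synthesis genes were not called (21 genes, median -0.07, adjusted p = 0.0776), with EBP at -0.55, SQLE at -0.46, FDPS at -0.45 and HMGCS1 at 0.37. Ribosomal protein genes, the brightest list, did not shift (37 genes, median 0.0014 but mean -0.0066 and a test direction downward, adjusted p = 0.665), with RPL6 at -0.17.

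Among 54 actin and tubulin cytoskeleton genes 2 were lower adjusted over the list alone, the microtubule-destabilizing STMN1 (-0.59) and the ARP2/3 subunit gene ARPC1B (-0.47), and TUBG1 was at -0.45. The list's median was -0.13 (adjusted p = 0.000403, and adjusted p = 0.384 with an estimated correlation), and with cyclic loess its median was -0.06 (adjusted p = 0.0683). After quantile normalization the median was -0.08. Of 36 integrins and adhesion genes 5 were lower and 1 higher adjusted over the list alone, including ITGA4 (-0.60), CD58 (-0.50) and ITGAE (-0.37). The list's median was -0.10 (adjusted p = 0.0155, and adjusted p = 0.384 with an estimated correlation). Its call ended in 5 alternatives, among them without the donor block (adjusted p = 0.0651), without donor 2 (median -0.07, adjusted p = 0.102) and with cyclic loess (adjusted p = 0.267). Without donor 3 its median was -0.07 as well, and it was -0.02 after quantile normalization, -0.04 with cyclic loess, -0.16 with median centring and -0.06 with the mean of a gene's probe sets.

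Markers of other cell types moved with the groups in part. Monocyte and macrophage markers had a higher mean in 18 of 19 genes (median 0.18), with FCGR2A at 0.42 and CD163 at 0.29, and 0 passed adjusted over the list alone. Their mean log2 value over the list was 5.51, the lowest of the 33 lists, and the call (adjusted p = 0.00405, and adjusted p = 0.384 with an estimated correlation) ended with cyclic loess (median 0.07, adjusted p = 0.139) and after quantile normalization (median 0.10, adjusted p = 0.139). Platelet and erythroid markers were higher in 11 of 11 genes by mean (median 0.14), with HBB at 0.26 and SLC4A1 at 0.25, and 0 passed adjusted over the list alone (list adjusted p = 0.0224, and adjusted p = 0.384 with an estimated correlation). That call ended without donor 1 (adjusted p = 0.0554), without donor 3 (adjusted p = 0.0574) and with cyclic loess (median 0.08, adjusted p = 0.121), and the median was 0.08 with median centring. B-cell markers had a median of -0.13, with PAX5 (-0.74) and CD72 (-0.49) lower adjusted over the list alone and MS4A1 at -0.37 (15 genes, list adjusted p = 0.0151, and adjusted p = 0.516 with an estimated correlation). Their call rested on donor 1, without which the median was 0.05, against the direction of the test, and the adjusted p 0.390. The median was -0.30 without donor 2, -0.21 without donor 3 and -0.21 with the mean of a gene's probe sets, and the call ended without the donor block (adjusted p = 0.0566). Dendritic cell markers were not called (13 genes, median 0.13 and test direction upward but mean -0.01, adjusted p = 0.818), with CCL22 and CCL17 (-0.62) lower adjusted over the list alone and CD209 at 0.26.

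In all 20 of the 33 lists were called with the preset correlation, 17 lower and 3 higher, and 0 with an estimated correlation. The count of 0 cannot tell whether correlation between members made the calls, since that setting rests on 2 residual degrees of freedom. The estimated correlation was 0.429 for the S phase list but -0.028, below the preset 0.01, for death receptors, and neither was called. The fry test found 0 lists that moved on balance in 1 direction and 20 that changed in either direction at an adjusted p under 0.05. These were not the same 20 lists that camera called. In fry's test of either direction the S phase list (adjusted p = 0.0528), G2 and mitosis (0.177), oxidative phosphorylation (0.139) and glycolysis (0.0528) did not pass. Hypoxia response genes (0.00019), natural killer markers (0.0022) and immediate-early genes (0.0080), which camera did not call, passed it.

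The change also depended on how bright a gene was. With genes sorted by mean log2 value into 10 bins, bin 4 had a median change of 0.12 (mean of the donors) and bin 9 one of -0.10. The trend was widest in donor 3, from 0.19 in bin 4 to -0.18 in bin 9, and narrowest in donor 2, from 0.04 to -0.03. After cyclic loess the medians of the bins lay between -0.02 and 0.01. Hybridization controls averaged over 18 probe sets were 0.16 ± 0.13 higher on the MMG arrays (higher in 3 of 3 donors, exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow). The 3' minus 5' difference of GAPDH, a sign of RNA integrity, was 0.32 ± 0.09 in static and 0.34 ± 0.15 in MMG cultures, and that of ACTB -0.46 ± 0.14 and -0.53 ± 0.12 (exact sign-flip permutation p = 0.75 and 0.5).

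**Figure D3:**
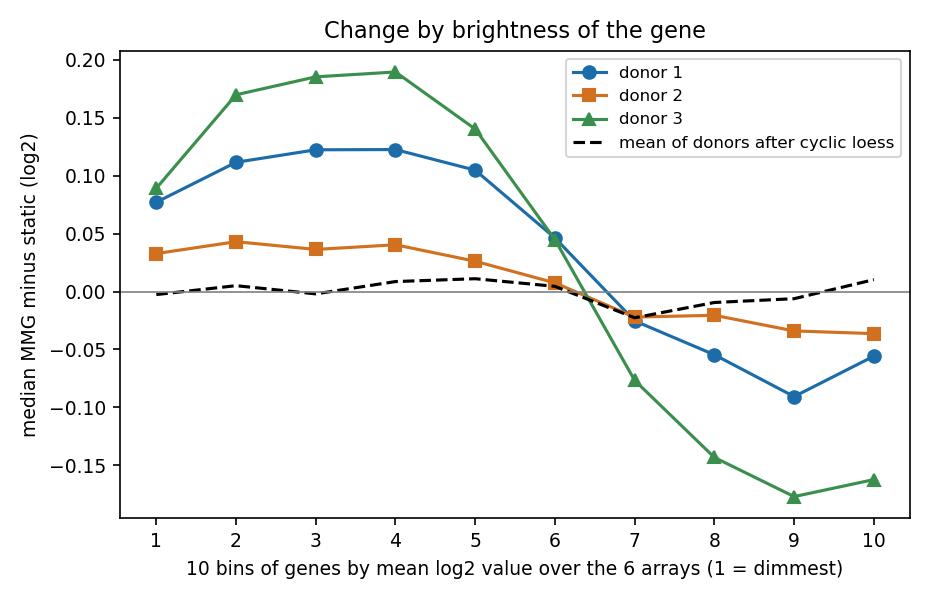
Median MMG minus static change on the log2 scale (vertical axis) in 10 bins of the 11939 genes sorted by mean log2 value (horizontal axis, dimmest first), with 1 solid line per donor and a dashed line for the mean of the donors after cyclic loess. Dimmer genes lie above 0 and brighter genes below 0 in each donor, most in donor 3, and the dashed line stays between -0.02 and 0.01.

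By size alone, 36 genes differed by at least 1.5-fold in the same direction in all 3 donors, 4 higher and 32 lower. They included all 17 genes that passed the test. Among the 19 that did not were GZMB, TFRC and CIRBP, a cold-inducible RNA-binding protein like RBM3 (-0.93 ± 0.34, adjusted p = 0.0562, chosen after its value was seen). Turning round the differences of donor 1, 2 or 3 left 0, 0 and 6 genes. With donor 1, 2 or 3 left out, and so only 2 donors to meet the criterion, the count was 51, 155 or 86. Across genes, the differences of donors 1 and 2 correlated at 0.435, of donors 1 and 3 at 0.578 and of donors 2 and 3 at 0.171, though genes are not independent replicates. The median SD between donors within a group was 0.14, the median SD of the 3 donor differences 0.16, and the median size of the mean change 0.14.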

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

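Cyclic loess was chosen after seeing the data. The 17 genes past the threshold kept their sign in all 12 alternatives that refit them. Several of these could not turn a sign. The block, the filter and the trend leave a gene's mean change as it is, and all 3 donors shared its sign when 1 was left out. All 17 remained past the threshold without donor 2, with median centring, the filter on dim probe sets or the trend of the prior variance, and without x_at probe sets. With cyclic loess 15 remained, without donor 1 or with the mean of a gene's probe sets 14, after quantile normalization 7, and without donor 3 3. The count of such genes was 0 without the replicate block that pairs cultures by donor, against 17 with it. It was 0 with an offset of 16 on the linear scale (2460 genes at an unadjusted p under 0.05 in limma), 2 with each probe set on its own, 7 after quantile normalization, 145 with the trend, 154 with the filter (of 7163 genes), 185 with median centring and 475 at an adjusted p under 0.10. It ranged from 3 to 952 with 1 donor left out. The count of genes changed 1.5-fold in all 3 donors was 1 at 2-fold, 202 at 1.3-fold and 51 to 155 with 1 donor left out. The cause was not tested. The monocyte list was not tested with the filter, which left too few of its genes, and the 1.5-fold count uses neither the block nor the trend. Of 1558 checks of named genes 1256 kept their call and direction, 248 came to pass the threshold, 49 no longer passed it and 5 turned. No detection call was used, so dim genes carry an unknown share of background.

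List medians are given where a call ended, appeared or turned; the report gives those that moved by over 1.5 times with the call kept. The test compares a list with all other genes, so a median can keep its sign while the call turns. With an estimated correlation 0 lists were called, and the medians, which this choice leaves as they are, were -0.13 for anti-apoptotic genes, -0.15 death receptors, -0.21 activation markers, -0.11 receptor signalling, -0.11 cytokines, -0.11 chemokines, -0.26 NF-kB, -0.19 interferon-stimulated genes, -0.16 cytotoxic granule genes, -0.47 S phase, -0.36 G2 and mitosis, -0.21 cyclins D, 0.082 heat shock proteins, -0.19 glycolysis, -0.18 oxidative phosphorylation, -0.13 cytoskeleton, -0.10 integrins, 0.18 monocyte markers, -0.13 B-cell markers and 0.14 platelet markers. Without the replicate block 6 of these calls ended at the same medians: anti-apoptotic genes, cytokines, cytotoxic granule genes, heat shock proteins, integrins and B-cell markers.

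After quantile normalization calls ended for anti-apoptotic genes (-0.097), receptor signalling (-0.0081), integrins (-0.019), monocyte (0.095) and platelet markers (0.11). They appeared for endoplasmic reticulum stress (0.095), oxidative stress (0.15) and natural killer markers (-0.14), and uncalled lists turned: pro-apoptotic genes (0.014), caspases (0.061), kinase C isoforms (0.076) and dendritic markers (0.050). With cyclic loess calls ended for anti-apoptotic genes (-0.12), receptor signalling (-0.013), cytotoxic granule genes (-0.088), glycolysis (-0.11), cytoskeleton (-0.065), integrins (-0.038), monocyte (0.069) and platelet markers (0.081). They appeared for endoplasmic reticulum stress (0.095), oxidative stress (0.12) and natural killer markers (-0.14), and pro-apoptotic genes (-0.0054), caspases (0.018), kinase C isoforms (0.051), ribosomal proteins (0.027), lineage regulators (0.031) and dendritic markers (0.022) turned. With median centring the call ended for anti-apoptotic genes (-0.18) and appeared for oxidative stress (0.011), and caspases (-0.077) and the gene PRF1 (-0.024) turned.

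With the filter on dim probe sets calls ended for anti-apoptotic genes (-0.14), receptor signalling (-0.11), integrins (-0.12) and B-cell markers (-0.17) and appeared for oxidative stress (0.060), and pro-apoptotic genes (-0.047), caspases (-0.020), ribosomal proteins (0.00025) and dendritic markers (-0.017) turned. With the mean of a gene's probe sets calls ended for anti-apoptotic genes (-0.052) and cyclins D (-0.059). Without x_at probe sets the call of platelet markers (0.13) ended, those of oxidative stress (0.15) and natural killer markers (-0.26) appeared, and the gene TNFRSF4 (0.098) turned. With the trend that of natural killer markers (-0.11) appeared.

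With 1 donor left out, medians ranged from -0.020 to 0.0090 for pro-apoptotic genes, -0.21 to -0.018 anti-apoptotic genes, -0.016 to 0.053 caspases, -0.0090 to 0.13 p53 targets, -0.036 to 0.035 kinase C isoforms, -0.16 to -0.0042 cytokines, 0.11 to 0.16 heat shock proteins, -0.031 to 0.11 endoplasmic reticulum stress, -0.20 to -0.099 glycolysis, 0.046 to 0.16 oxidative stress, -0.094 to -0.065 integrins, -0.040 to 0.053 ribosomal proteins, -0.12 to -0.012 lineage regulators, -0.30 to 0.047 B-cell, -0.15 to -0.031 natural killer, 0.036 to 0.20 dendritic and 0.10 to 0.16 platelet markers. PRF1 ranged from -0.018 to 0.073, and CD3E and CD7, chosen after their values were seen, from -0.63 to 0.64 and from -0.93 to 0.40, none past the threshold.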

Other observations

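Among the genes changed at least 1.5-fold in all 3 donors were several that the report does not name, described here after their values were seen. CENPU (-0.999 ± 0.45) and ITGB3BP (-1.01 ± 0.35) encode centromere proteins and DTL (-0.90 ± 0.34) an adaptor of replication control, and none of the 3 passed the test (adjusted p between 0.0519 and 0.0595 in limma). BASP1 differed by -1.04 ± 0.40 and VPS13B by -1.21 ± 0.51 (adjusted p = 0.0562 for each). The interferon-induced genes IFI44L (-0.84, adjusted p = 0.0652), a member of the fixed interferon-stimulated list, and EIF2AK2 (-0.66, adjusted p = 0.0511), which is in none of the fixed lists, were also in this set.

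Clustered histone genes were taken as a group by symbol, which let in a few outside the clusters such as H1-10. The group was formed, and compared as below, only after H2AC6 and H2BC5 had been seen. The 40 others were mostly dim (mean log2 value 5.89), and dim genes lay higher in MMG in general. Their median change was 0.133, against a median of 0.09 and a 95th percentile of 0.126 for 10000 random lists matched on brightness, which ignore correlation between members, and 22 were higher and 0 lower in all 3 donors. Of all genes 27.9% were higher in all 3. The largest changes among the 40, H2BC12L (0.49) and H2BC9 (0.45), came from x_at probe sets, which can also bind related transcripts such as that of H2BC5. H1-2 (0.38), from another type of probe set, followed. After cyclic loess the median of the 40 was 0.0547, against 0.01 and 0.0506, with 13 of the 40 higher and 2 lower in all 3 donors and a median of 0.08, 0.16 and 0.0094 in donors 1, 2 and 3. None of the 40 passed the test in limma, so beyond brightness the group's difference was small and smallest in donor 3. Most histone mRNAs carry no poly(A) tail, and the part of these signals that comes from tailed transcripts was not measured.

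The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so the count of splits can neither exclude chance nor show it. The real split gave 17 genes past the threshold and the highest other split 0, so that 1 of 10 splits gave as many. Only 4 of these part all 3 pairs, and 1 of those 4 gave as many. Splits that part only 1 pair are a poor comparison for gene counts too, for the reason given below. For genes changed 1.5-fold in the same direction in all 3 donors, a count made only for the 4 splits that part all 3 pairs, the real split gave 36 and the highest other 6, so that 1 of 4 gave as many. For list calls with the preset correlation the real split gave 20 and the other 3 splits that part all 3 pairs gave 16, 10 and 6. Over all 10 splits 3 gave as many as 20, but the 2 others part only 1 pair. With the donor block such a split takes its estimate from that donor's own difference between MMG and static culture, so it is no grouping without the treatment.

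Of the tests that follow, those of a lower share of T cells and of cytotoxic lymphocytes were chosen after the values were seen, and the count of 1.5-fold genes over splits above was too. Single genes named below outside the naming rule were chosen after their values were seen. The other tests were fixed before their results were computed, on patterns already noticed in these data.

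RBM3 and CIRBP, both induced by cold, were lower in all 3 donors. A compressed brightness range on the MMG arrays is argued against, since after cyclic loess the smaller of the changes, that of CIRBP, was still -0.82, and both genes lay below -0.5 in each donor. Warmer MMG cultures are a candidate explanation that predicts higher heat shock factor targets, and 20 such genes outside the fixed lists had a median change of 0.12, at percentile 99.65 of 10000 random lists matched on brightness. The random lists ignore correlation between members, so the percentile is weak support. The fixed heat shock list had adjusted p = 0.431 with an estimated correlation in limma's camera, a setting that few lists could pass with 2 residual degrees of freedom. Members went from FKBP4 (0.43) to CHMP2A (-0.36), 0 passed the test, 9 of the 20 were higher and 3 lower in all 3 donors (27.9% of all genes were higher in all 3), and the list's median was 0.06, 0.23 and 0.0045 in donors 1, 2 and 3; temperature was not measured here, and another stress that induces chaperones, or MMG itself, stays open.

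The median of the S phase list was lower in all 3 donors. A compressed brightness range is argued against: after cyclic loess the list's median was -0.71, -0.28 and -0.36 in donors 1, 2 and 3, a mean of -0.45. A lower share of T cells could lower these genes if other cells divide less. The median of 8 T-lineage genes lay 0.30 above that of the S phase list on average, by 0.58 and 0.48 in donors 1 and 3, but 0.17 below it in donor 2, so it cannot be told apart from a fall of S phase genes within T cells. A slower cell cycle in MMG stays open, as does a lower share of B cells, whose markers had medians of -0.47, -0.02 and -0.23 in donors 1, 2 and 3, and neither was tested beyond these values.

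GNLY, GZMA, GZMB, GZMM and GZMH (-0.59) were lower in all 3 donors, whereas GZMK was at 0.10. A lower share of cytotoxic lymphocytes would lower their other transcripts alike. In 12 other cytotoxic genes the median changed by -0.050 on average over donors and by -0.06, -0.16 and 0.07 in donors 1, 2 and 3. This list was chosen after the values were seen, without the granzymes and GNLY that raised the question. It therefore argues only weakly against a lower share. This list left out XCL1, lower in all 3 donors (-0.63), but with XCL1 and the rest of the cytotoxic and natural killer lists except granzymes and GNLY, 19 genes in all, the median was -0.04, -0.13 and -0.09. The 12 genes had an SD of 0.233 and went both ways, with CST7 at 0.38 and PRF1 at 0.03, but CTSW at -0.55 and NKG7 at -0.28, both lower adjusted over the cytotoxic granule list alone. Compression of the brightness range is argued against by a mean change of GNLY and GZMA of -0.73 after cyclic loess, below -0.5 in each donor, and a change of these transcripts within the cells that make them may remain as a hypothesis, found and tested on the same data.

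HMOX1, FTL and NQO1 are known targets of the transcription factor NRF2, and a wider rise of its targets was tested as a hypothesis. The median change of 28 other targets was 0.09, at percentile 95.73 of brightness-matched random lists, which ignore correlation between members and whose 95th percentile was 0.08. The margin was small: 8 of the 28 genes were higher in all 3 donors, close to the 27.9% of all genes that were, 2 were lower in all 3, and 0 passed the test. The list's median was 0.15, 0.03 and 0.05 in donors 1, 2 and 3, so a wider rise was at most weak in these 28 genes. They were taken from outside the fixed lists, which left out targets such as GCLC (0.37) and TXNRD1 (0.54), both higher in all 3 donors. Of the 25 measured genes of the fixed oxidative stress list, GCLC, TXNRD1, HMOX1, FTL and NQO1 were higher adjusted over the list alone. The other 20 did not pass, and that list as a whole was not called.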
